A study of Rattus norvegicus with 6 samples.

How the data were processed

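Pancreas tissue of male Sprague-Dawley rats, an outbred laboratory strain, 8 weeks old, was profiled by bulk RNA sequencing in 6 samples. The labels name 3 samples with L-arginine-induced acute pancreatitis (AP) and 3 saline controls. Per the labels' protocols, poly(A) RNA was enriched with Oligo(dT) beads, broken into fragments of about 300 bp and sequenced on an Illumina instrument with 150 bp reads. Strand marking is not given in the sources used here.

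The deposited table holds whole-number counts of reads per gene, not normalised, as the differing column totals show. Per the submitters' processing notes, the authors worked with FastQC, STAR, featureCounts and DESeq2 and with the rat build mRatBN7.2. The notes give no versions, and the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads of near-identical genes, such as the trypsinogens, the amylases, both insulin genes, the Reg family, the globins and the ribosomal proteins, could therefore be split between copies or lost, and reads of overlapping genes on opposite strands cannot be told apart. The table names genes by symbol only and no coordinates are printed. Of 23096 rows, 3110 carry no gene name, and these stayed out of library sizes and tests. They held 5.48%, 6.61% and 7.69% of the counts of control replicates 1 to 3 and 1.42%, 1.41% and 2.10% of those of AP replicates 1 to 3. The rows of 185 symbols that occurred on several rows (391 rows) were summed, which left 19780 symbols. Of these, 16799 matched a RefSeq gene table of assembly GRCr8, which was used only for names and for which genes lie next to each other.

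Column totals over all rows were 18196636, 17819149 and 14453584 counts in control replicates 1 to 3 and 18393266, 18961353 and 17404247 in AP replicates 1 to 3. Intervals and floors from counts cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Every pair of libraries within a group differed by more than sampling noise (chi-square per gene of 44.0 to 199 over 9523 genes), so no library was treated as a repeat of another.

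The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, edgeR's default filter on low counts and Benjamini-Hochberg adjustment, with genes called at an adjusted p of 0.05. It compared the 3 AP with the 3 control samples, with no covariate. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of F. Normalised CPM were taken with edgeR's cpm function from the TMM-scaled library sizes, which were 0.470 times the total in controls and 2.13 times in AP samples, so normalised CPM are not shares of reads. A fold change is therefore relative to the middle of the tested genes. Where a group held no count of a gene, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio of pooled normalised counts is given with its exact 95% Poisson interval. Shares of counts refer to rows with a gene name and were compared with a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1. The labels do not say in words that each sample came from a separate animal, so p-values measure the spread between these samples, except where genes are named as the units.

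Before the data were examined, the design, 23 gene lists, the alternatives and a rule for named genes were fixed. The rule took, in each direction, the 8 genes with the largest log2 fold change among called genes with a mean logCPM of at least 2, a proper symbol and no overlap between the groups, the 2 called genes with the highest expression, and from each list the 3 members with the lowest p. Some genes that the rule takes are not reported here. Other genes named in the text were chosen after their values were seen. Of 508 listed members, 486 were found in the table. Lists were tested against all other tested genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, on logCPM with a prior count of 2, and again with an estimated correlation, with adjustment over the lists. The fry test asks a different question, whether a list's genes move on balance in 1 direction, and compares them with no other genes. Counts of list members come from the adjustment over all tested genes, and those adjusted over the list alone are given where they differ. A further 7 lists were written after the data had been seen and appear only in the closing section.

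The alternatives were DESeq2 size factors, upper quartile scaling, library totals alone, TMM without the acinar genes, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, no filter and a filter of 50 counts in 3 samples, the replicate number as a block, 1.5-fold and 4-fold thresholds, and each library left out in turn. Keeping the unnamed rows, leaving out symbols on several rows and adding genes to the digestive enzyme share were chosen after seeing the data. The analysis was tested on simulated data made from these libraries for the comparison of AP with control, with 13103 genes in the fit. It recovered 57% of 100 genes changed 2-fold and 100% of 99 genes changed 4-fold, and called 0.0465% of 12904 unchanged genes. A raised list was called by camera, and 0 of 20 random lists were. The simulation gave both groups the same mean profile apart from a small set of genes changed in random directions. It used a common dispersion and drew genes independently. It therefore does not test the scaling under a change as wide as that between these groups, or correlation within lists.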

Results

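Bulk RNA sequencing counted poly(A) transcripts in 6 samples of male rat pancreas, 3 with acute pancreatitis (AP) induced with L-arginine and 3 saline controls. L-arginine in excess injures the exocrine pancreas and is a standard rodent model of AP. The sample labels give a dose of 5 mg/kg and 36 hours of treatment, whereas the design text gives 2 injections of 2.5 g/kg and 48 hours, and the labels do not settle which applied. Control libraries held 18196636, 17819149 and 14453584 counts and AP libraries 18393266, 18961353 and 17404247. The comparison asks which transcripts differ between AP and control pancreas.

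In AP pancreas, transcripts of digestive enzymes and of acinar identity fell, while those of leukocytes, inflammation and extracellular matrix rose. Prss1, a trypsinogen gene, fell 65.5-fold and Lyz2, the lysozyme of macrophages and neutrophils, rose 62.3-fold (n = 3 per group). Of 13240 tested genes, 8552 (64.6%) were called by edgeR's quasi-likelihood test, 4520 higher and 4032 lower in AP, and 5717 of them differed at least 2-fold (3209 higher, 2508 lower). At least 16-fold differences numbered 578 higher and 286 lower. The groups did not overlap in 70.9% of tested genes and in 98.4% of called genes, where chance gives 10% of tested genes. The split of directions is relative to the scaling. With library totals alone the median log2 fold change of the tested genes moved by 2.18, and 11680 genes were higher and 572 lower (95.3% higher, against 52.9% with TMM). Sizes depend on the scaling as well. The log2 fold change of Prss1 was -6.03 with TMM and -3.92 with library totals, and that of Lyz2 was 5.96 and 8.14. TMM-scaled values are given throughout, and directions that turned with library totals are named.

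The largest rises by rule were in genes with hardly any control counts. No control library held a count of Slc4a5, a bicarbonate cotransporter (2053 counts in AP, at least 132-fold higher), Krt17, an epithelial keratin (at least 114-fold), Ccl12, a monocyte chemoattractant (at least 98.4-fold), Dsg3, a desmosomal cadherin (at least 93.4-fold), Cthrc1, a secreted matrix protein (at least 69.4-fold), or Mmp9, a gelatinase (at least 53.9-fold). Wfdc18 had 1 control count, in replicate 3, and 1546 AP counts, a ratio of 299 (95% counting interval 53.6 to 11800), and of 125 without AP replicate 2, 190 and 192 without control replicates 1 and 2, and at least 71.7 without control replicate 3. Without 1 control library the bounds of the genes with no control count shrank to between 0.637 and 0.722 of these values, and that of Dsg3 shrank to 63.1-fold without AP replicate 2. Angptl4, an inhibitor of lipoprotein lipase, reached 44.4 ± 7.11 normalised CPM in AP against 4 control counts, all in replicate 3 (log2 fold change 7.89 ± 0.525 SE, and 7.26 and 7.27 without control replicates 1 and 2). Without control replicate 3 no control count of Angptl4 was left, so no size is given for that fit. The largest falls were in Tinag and Clca1, each with 1 AP count, in replicate 3 (ratios of 2670, interval 478 to 106000, and 2010, interval 359 to 79600, or at least 627-fold and 472-fold without that library), Azgp1 with 3 AP counts, all in replicate 3 (ratio 539, interval 183 to 2630, or at least 380-fold without it), Acsm1, Amy1a, Aadat, Cuzd1 and Rnase1. The ratios of Tinag, Clca1 and Azgp1 were 1730, 1300 and 349 without AP replicate 1 and 1740, 1310 and 350 without AP replicate 2. Among the last 5, log2 fold changes ran from -9.03 ± 0.645 for Acsm1 to -8.17 ± 1.09 for Rnase1. Without AP replicate 3 they were -9.41 for Amy1a, -10.24 for Cuzd1 and -9.49 for Rnase1. Acsm1 (0 and 0.0249 normalised CPM) and Aadat (0.0247 and 0.0249) had hardly any counts in AP replicates 1 and 2, so no size is given for them there. Acsm1 was at -8.42 without AP replicate 1.

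Digestive enzyme transcripts made up most of the control libraries and little of the AP libraries. Their list took 62.0%, 62.2% and 61.5% of the counts in control replicates 1 to 3 and 1.01%, 1.06% and 7.2% in AP replicates 1 to 3. The means were 61.9% ± 0.374 and 3.09% ± 3.56 (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). Of the genes, 19 of 20 tested members fell and none rose, and the exception was the trypsinogen gene Try10 (log2 fold change -3.86 ± 1.80, adjusted p = 0.0893, at -0.06 without control replicate 1, -5.05 without AP replicate 3 and called without control replicate 3, at -4.44). The call of Try5 (-4.37 ± 1.48) ended with library totals (-2.255, adjusted p = 0.128) and without control replicate 1 (-2.45, 0.13) or AP replicate 1 (-4.03, 0.0924). The median log2 fold change of the list was -6.62 (camera adjusted p = 3.75e-07, adjusted p = 0.362 with an estimated correlation), or -4.49 with library totals. Ctrb1, chymotrypsinogen B, went from 168500 ± 33300 to 3597 ± 4250 normalised CPM (46.8-fold) and Prss1 from 164900 ± 23400 to 2517 ± 2900 (65.5-fold). These were the 2 genes with the highest expression among those that fell. Pancreatic amylase Amy2a3 (log2 fold change -7.48 ± 0.822) and colipase Clps (-6.64 ± 0.929) fell as well. AP replicate 3 kept more of these transcripts than the other AP libraries. Without it the list median was -8.08, Ctrb1 was at -7.21, Prss1 at -7.62, Amy2a3 at -8.60 and Clps at -7.94.

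**Figure D1:**
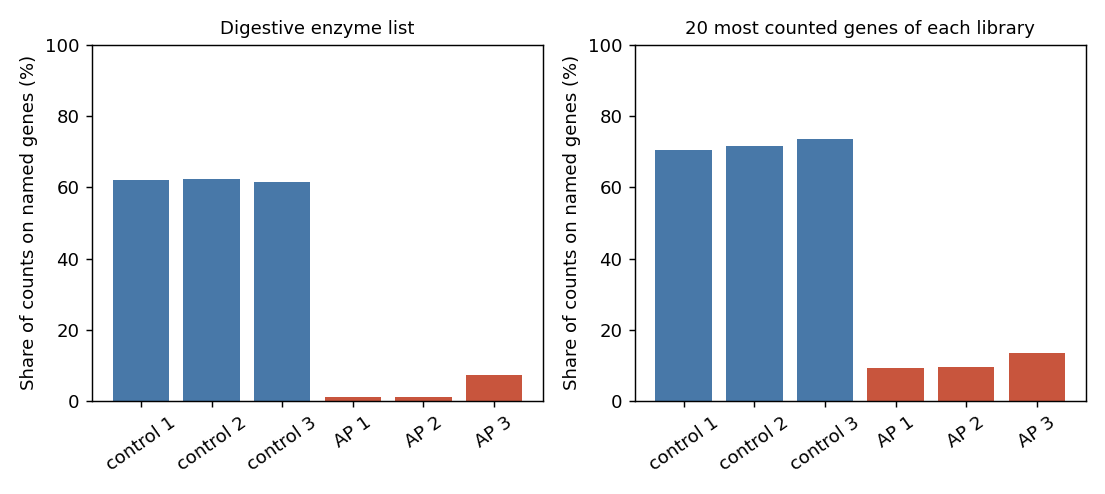
Share of counts on named genes (%, vertical axis) in each library, with 1 bar per library (blue control, red AP), for the digestive enzyme list on the left and the 20 most counted genes of each library on the right. The enzymes took 61.5% to 62.2% in controls and 1.01%, 1.06% and 7.2% in AP, and the 20 top genes took 71.9% ± 1.52 and 10.7% ± 2.32 (mean ± SD, n = 3).

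Most genes of acinar transcription factors and granule proteins fell with the enzymes. Of 24 tested genes of acinar identity and the secretory granule, 23 fell, with a median of -5.51 (camera adjusted p = 4.13e-09, adjusted p = 0.362 with an estimated correlation), and the median was -7.35 without AP replicate 3. Xbp1, a regulator of secretory capacity, fell by 3.60 ± 0.252 on the log2 scale, and Rab3d, a zymogen granule GTPase, by 3.99 ± 0.227. Itpr3, a calcium release channel, fell by 2.01 ± 0.158, with a sign that turned to 0.17 (not called) with library totals. Among genes picked after their values were seen, Ptf1a, which drives acinar enzyme expression, fell by 5.29 ± 0.942 and Bhlha15 by 6.04 ± 0.959 (-7.54 and -8.08 without AP replicate 3). The exception was Vamp8, a granule SNARE (log2 fold change -0.01 ± 0.11, adjusted p = 0.937, and 2.16 with library totals).

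Islet genes mostly did not pass the test, in either direction. Of 24 tested, 4 rose and 1 fell (2 and 0 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.26), whereas with library totals all 24 rose. Ins1, insulin 1, was at 445 ± 60.6 normalised CPM in AP and 333 ± 113 in controls (adjusted p = 0.173; called without control replicate 1, at 0.71), and Ins2 at a log2 fold change of 0.34 ± 0.226 (adjusted p = 0.218). Among the risers were the glucose transporter gene Slc2a2 (0.97 ± 0.233), Chgb and Pyy. Iapp, islet amyloid polypeptide, fell by 0.70 ± 0.242, and rose by 1.47 with library totals. The calls of Chgb, Pyy and Iapp each ended in at least 4 of the 6 fits that left out 1 library, with adjusted p of up to 0.113, 0.102 and 0.129. Chgb, at 1.26, was at 2.04 without control replicate 1, and Pyy, at 2.22 (limma-voom adjusted p = 0.0524), was at 1.60 without control replicate 2 and 3.07 without control replicate 3.

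Of 21 tested ductal and metaplasia genes, 7 rose and 5 fell (camera adjusted p = 0.505), whereas with library totals 19 rose and 2 fell. Cd44, an adhesion receptor also carried by leukocytes, rose 31.4-fold (log2 fold change 4.97 ± 0.142), Anxa2 rose 16.4-fold (4.04 ± 0.136) and the ductal keratin gene Krt7 14.7-fold (3.88 ± 0.227). The 5 that fell were Tff2 (-6.71 ± 0.835, and -8.23 without AP replicate 3), Muc1 (-4.09 ± 0.366), Cftr, the duct chloride channel, Hes1 and Onecut1, and the last 3 rose with library totals (1.06, 0.70 and 0.96). Of the 4 tested regenerating protein genes, which encode secreted C-type lectins of injured pancreas, Reg1a fell (log2 fold change -3.87 ± 1.43, adjusted p = 0.0416, and none adjusted over the list alone), and stood at -7.19 without AP replicate 3. This call ended with library totals (-1.77, adjusted p = 0.204) and without any 1 of the control libraries or AP replicate 1 (adjusted p of 0.0536 to 0.114, with -3.07 without control replicate 1). Reg3g (4.01 ± 1.59), Reg3a (-1.96 ± 1.75) and Reg3b (-0.37 ± 1.60) were not called by the main test. Reg3g was called with the replicate block (3.67, adjusted p = 0.000388), without a filter (4.07, adjusted p = 0.0395) and with library totals (6.10, adjusted p = 0.00465). Without AP replicate 3 Reg3a and Reg3b fell (-6.08 and -4.10) and Reg3g was at 1.06, and Reg3g rose without AP replicate 1 or 2 (4.50 and 4.57). The list was not called (camera adjusted p = 0.582) except with library totals, as lower than other genes (0.00204), and its median of -1.17 became 0.93 with library totals, 1.75 without control replicate 1 and -5.09 without AP replicate 3.

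Of the tested members of the leukocyte lists, all but Prf1 rose in the edgeR test. All 22 monocyte and macrophage genes rose, with a median of 5.14 (camera adjusted p = 1.11e-10, adjusted p = 0.178 with an estimated correlation). Lyz2 and the cytoskeletal gene Actb had the highest mean expression of the genes that rose, with Lyz2 at 3761 ± 233 normalised CPM in AP against 60.3 ± 5.77 (62.3-fold). Ccr2, the monocyte chemokine receptor, rose 45.5-fold (5.51 ± 0.190), Fcgr1a 35.4-fold (5.15 ± 0.192) and the adaptor gene Tyrobp 35.2-fold (5.14 ± 0.157). Gpnmb, picked after its values were seen, reached 1944 normalised CPM from 9.17 (log2 fold change 7.75 ± 0.657, and 8.75 without control replicate 3). All 14 tested neutrophil genes rose, with a median of 5.20 (camera adjusted p = 1.08e-06, adjusted p = 0.178 with an estimated correlation). They included Ncf1 of the NADPH oxidase (5.79 ± 0.202), which macrophages also express, and Selplg (4.93 ± 0.207). The list members S100a8 and S100a9 stood at 11.6 and 25.3 normalised CPM in AP, and limma-voom did not call S100a9 (adjusted p = 0.0748).

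Of 17 tested lymphocyte genes, 16 rose (17 adjusted over the list alone), with a median of 3.11, or 2.83 with the 3 genes that had no control count set at their bound (camera adjusted p = 0.000424, adjusted p = 0.362 with an estimated correlation and 0.546 with library totals). Prf1, perforin, was the exception (2.62 ± 1.09, adjusted p = 0.0624). It was called by DESeq2 (adjusted p = 0.011), without a filter (0.0485), with library totals (0.00194) and without AP replicate 1 (3.11), and stood at 4.08 without control replicate 2 and 1.43 without AP replicate 3. Cd8a rose by 6.00 ± 0.664 (7.42 without control replicate 2) to 120 ± 65.5 normalised CPM and Cd8b by 4.99 ± 0.380 (5.67 without control replicate 2), while the T cell receptor subunit gene Cd3e stood at 9.25 in AP against 1.02 (3.12 ± 0.667, and 3.75 without control replicate 2, with limma-voom adjusted p = 0.0769). In rats CD8a is also carried by natural killer cells and by some macrophages. The B cell gene Fcer2 was at least 27.3-fold higher (18.6-fold without AP replicate 1, and 17.4-fold to 19.6-fold without 1 control library).

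**Figure D2:**
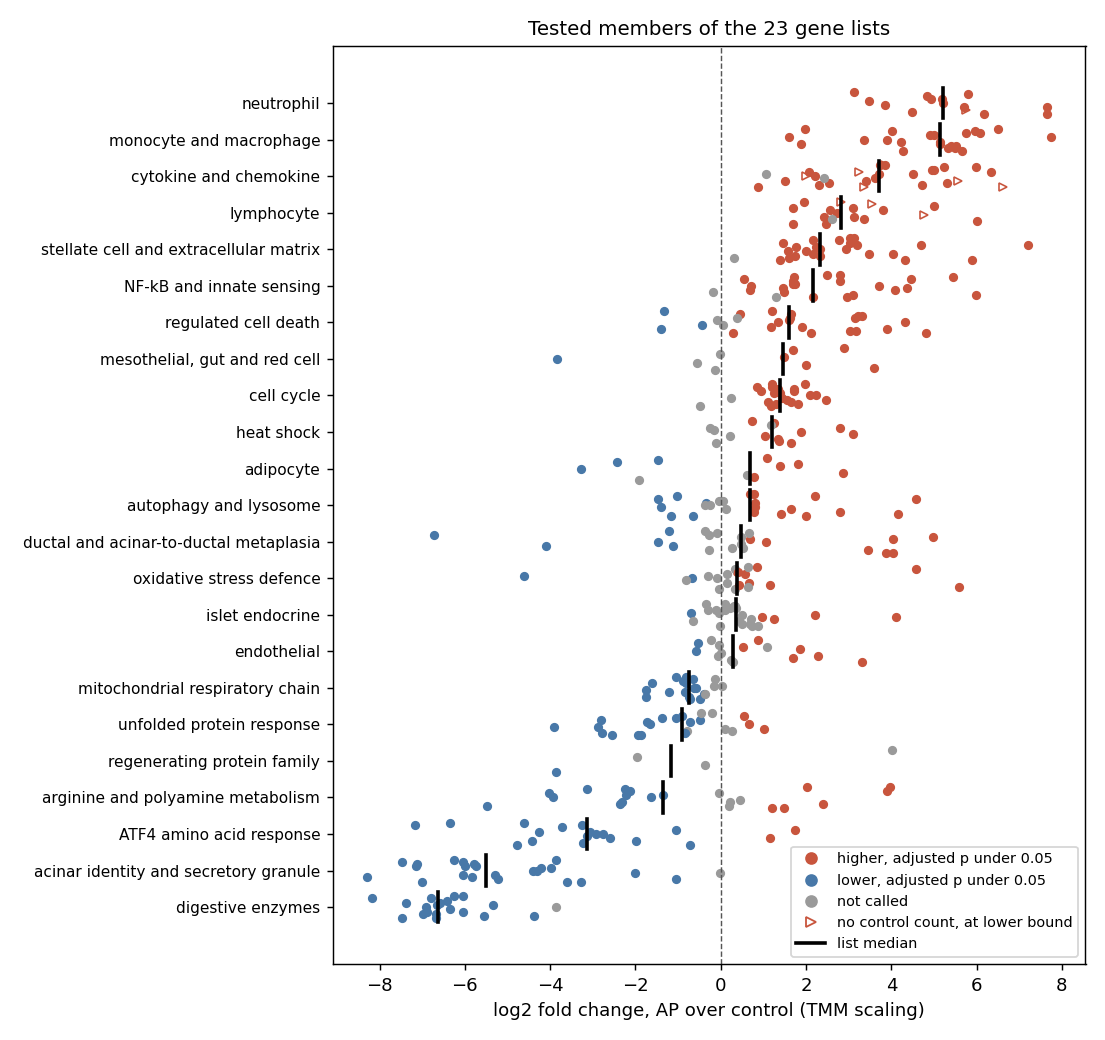
Log2 fold change of AP over control with TMM scaling (horizontal axis) for each tested member of the 23 gene lists, with 1 point per gene, coloured by call, open triangles at the lower bound for genes without a control count, and a black bar at the list median. Medians run from -6.62 for digestive enzymes to 5.20 for neutrophil genes, and those of the regenerating, unfolded protein, arginine and mitochondrial lists turn positive with library totals (0.93, 1.25, 0.81 and 1.44).

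Cytokine and chemokine genes rose in 25 of 27 cases, with a median of 4.50, or 3.70 with 6 genes at their bound and 3.85 without AP replicate 3 (camera adjusted p = 2.09e-07, adjusted p = 0.178 with an estimated correlation and 0.0541 with library totals). Tgfb1 rose 14.4-fold (log2 fold change 3.85 ± 0.134), Il18 37.3-fold (5.22 ± 0.208) and Il33, an alarmin of stromal cells, 12.3-fold (3.62 ± 0.184). Il6 was at least 10.2-fold higher (6.49-fold to 7.33-fold without 1 control library) and Il1b rose by 4.71 ± 0.632 (4.08 without control replicate 1). The exceptions were Cxcl9 and Cxcl11 (adjusted p = 0.211 and 0.0952), whose log2 fold changes of 1.06 and 2.42 rested on AP replicate 3 (-0.09 and -0.08 without it). Both were called without AP replicate 1 (1.52 and 2.96), and Cxcl11 without AP replicate 2 (2.88). In the list of NF-kB and innate sensing 21 of 23 genes rose, with a median of 2.16 (camera adjusted p = 5.1e-07, adjusted p = 0.178 with an estimated correlation), and the receptor gene Tlr2 (5.45 ± 0.249), Tnfaip2 (4.47 ± 0.248) and the inhibitor gene Nfkbie (3.10 ± 0.154) had the lowest p. Ptgs2 and Stat3 were not called (adjusted p = 0.149 and 0.479), although Ptgs2 passed without control replicate 3 (2.55), and Stat3 turned from -0.18 to 1.99 with library totals.

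Genes of regulated cell death rose in 18 of 24 cases and fell in 3 (24 and 0 with library totals), with a median of 1.61 (camera adjusted p = 0.000764, adjusted p = 0.362 with an estimated correlation). The pyroptosis effector Gsdmd (3.90 ± 0.180), the necroptosis kinase Ripk3 (4.82 ± 0.328) and Casp1 (3.32 ± 0.249), all of which leukocytes also express, had the lowest p. Among those that fell, Bcl2 (-1.41 ± 0.144) and Casp9 (-1.33 ± 0.176) rose with library totals (0.77 and 0.85). Autophagy and lysosome genes rose in 12 of 23 cases and fell in 6 (camera adjusted p = 0.186), whereas all 23 rose with library totals (camera adjusted p = 0.0232). The lysosomal genes Ctss (4.17 ± 0.162) and Ctsz (4.57 ± 0.183) were among those that rose, and Ctsb, cathepsin B, rose 6.91-fold to 2335 normalised CPM.

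Stress genes of the endoplasmic reticulum and of amino acid supply fell relative to other genes. In the unfolded protein response 15 of 23 genes fell and 3 rose, with a median of -0.92 (camera adjusted p = 0.000557, adjusted p = 0.362 with an estimated correlation), but the median was 1.25 with library totals, where 15 rose and 5 fell. Herpud1 (-2.81 ± 0.161) and Dnajc3 (-2.79 ± 0.214) were negative with either scaling, while Syvn1 (-1.93 ± 0.130) turned to 0.24. The 3 risers were the chaperone genes Calr (1.02 ± 0.252), Pdia3 (0.55 ± 0.171) and Pdia4 (0.66 ± 0.218), the last 2 of which were no longer called without control replicate 2 (adjusted p = 0.0808 and 0.0937) or AP replicate 2 (0.0806 and 0.083), nor Pdia4 without control replicate 3 (0.0868) or Pdia3 with the replicate block (0.059). In the ATF4 amino acid response 17 of 19 genes fell and 2 rose, with a median of -3.13, or -0.95 with library totals, where 12 fell and 4 rose (camera adjusted p = 4.89e-06, adjusted p = 0.362 with an estimated correlation). Vldlr (-2.94 ± 0.186), Gpt2 (-2.76 ± 0.196) and Ddit4 (-3.06 ± 0.233) had the lowest p, and asparagine synthetase Asns fell 27.3-fold (-4.77 ± 0.367). Atf3 (1.75 ± 0.503, with limma-voom adjusted p = 0.0809) and Cebpb (1.16 ± 0.249) rose.

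Of 21 tested arginine and polyamine genes, 11 fell and 6 rose, with a median of -1.36, whereas with library totals 11 rose and 4 fell, with a median of 0.81 (camera adjusted p = 0.0655). Camera called the list as lower than other genes with library totals (adjusted p = 0.000103) and without AP replicate 3 (0.0344). Gatm, which makes guanidinoacetate from arginine, fell from 2908 ± 568 to 64.9 ± 23.9 normalised CPM (44.8-fold), Gamt, the next enzyme of creatine synthesis, fell 15.3-fold (-3.93 ± 0.273) and the cationic amino acid transporter gene Slc7a2 fell by 2.25 ± 0.127, a call that ended with library totals (-0.07). Among the risers were arginase 1, Arg1 (1.21 ± 0.254), the inducible nitric oxide synthase Nos2 (3.90 ± 1.05, and 2.74 without AP replicate 3) and Ass1, which rebuilds arginine from citrulline (3.98 ± 0.706, and 2.99 without AP replicate 3). Neither Nos2 nor Ass1 was called by limma-voom (adjusted p = 0.175 and 0.0641).

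Mitochondrial respiratory chain genes fell in 17 of 21 cases, with a median of -0.75 (camera adjusted p = 1.41e-05, adjusted p = 0.362 with an estimated correlation), and all 21 rose with library totals (median 1.44). Ndufb5 (-1.75 ± 0.129), Ndufa4 (-1.75 ± 0.161) and Ndufs3 (-1.62 ± 0.152) had the lowest p, and turned to 0.43, 0.44 and 0.55. In oxidative stress defence 9 of 21 genes rose and 2 fell (camera adjusted p = 0.186), whereas with library totals 19 rose and 1 fell, and 6 rose without control replicate 2 or 3 or AP replicate 2 or 3. Heme oxygenase Hmox1 rose 48.3-fold (5.59 ± 0.300) and the glutathione peroxidase gene Gpx2 23.9-fold (4.58 ± 0.266), while the cystine transporter gene Slc7a11 fell by 4.61 ± 0.513 and Gpx4 by 0.68 ± 0.119, the latter rising by 1.5 with library totals. Heat shock genes rose in 9 of 14 cases and none fell, with a median of 1.21 (camera adjusted p = 0.00781, adjusted p = 0.362 with an estimated correlation). The small heat shock genes Hspb8 (3.09 ± 0.242) and Cryab (2.79 ± 0.311) and the co-chaperone gene Bag3 (1.64 ± 0.164) had the lowest p.

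**Figure D3:**
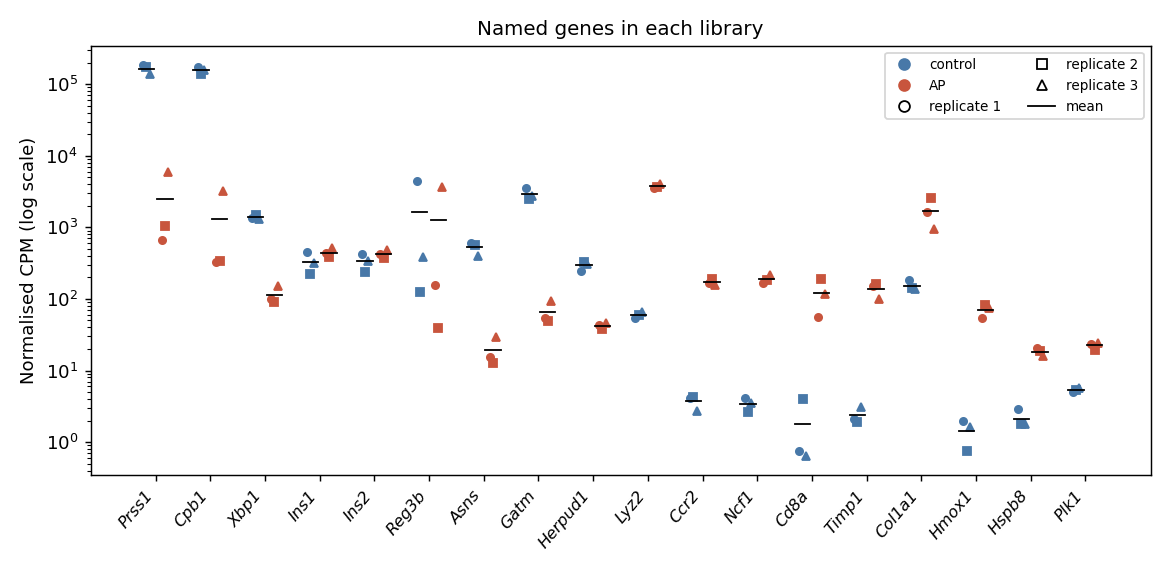
Normalised CPM (vertical axis, log scale) of 18 named genes in each library, with blue symbols for controls, red symbols for AP, shapes for the replicate number, which does not pair samples, and black lines for group means. Prss1 fell from 164900 to 2517 and Lyz2 rose from 60.3 to 3761, whereas Ins1 and Reg3b overlap between the groups.

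Matrix genes rose almost throughout. Of 25 genes of stellate cells and extracellular matrix 24 rose and Dcn, decorin, was not called (0.30 ± 0.238, adjusted p = 0.297), with a median of 2.32 (camera adjusted p = 4.13e-09, adjusted p = 0.362 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteinases, rose 59.1-fold (5.89 ± 0.271), Vim, vimentin, 16.6-fold (4.05 ± 0.230) and Mmp14 8.7-fold (3.12 ± 0.133). The collagen genes Col3a1 and Col1a1, picked after their values were seen, reached 2929 and 1715 normalised CPM from 627 and 153. Actb rose 8.08-fold to 3327 ± 605 normalised CPM. Cell cycle genes rose in 20 of 22 cases, with a median of 1.38 (camera adjusted p = 0.000125, adjusted p = 0.362 with an estimated correlation and 0.0693 with library totals), with Plk1 at 2.09 ± 0.163, Ccnd1 at 2.24 ± 0.213 and Aurkb at 1.73 ± 0.239.

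Markers of other tissues moved less evenly. Of 15 endothelial genes 6 rose and 2 fell (camera adjusted p = 0.157), whereas all 15 rose with library totals. Tie1 (2.27 ± 0.149), Eng (1.86 ± 0.139) and P-selectin, Selp (3.31 ± 0.340), had the lowest p. The VEGF receptor genes Flt1 (-0.54 ± 0.156) and Kdr (-0.59 ± 0.188) fell, rose with library totals (1.64 and 1.59), and were not called without control replicate 1 (adjusted p = 0.0578 and 0.091) or AP replicate 1 (0.0515 and 0.0724), nor Kdr without AP replicate 3 (0.0599). Of 10 adipocyte genes, Cfd, Cidea, Cidec, Fabp4 and Pnpla2 (0.77 ± 0.126) rose and Lpl (-1.46 ± 0.251), Pck1 and Tmem120b (-2.44 ± 0.207) fell (6 and 4 adjusted over the list alone). The median of 0.70, the mean of -0.06 and the fry direction differed in sign (camera adjusted p = 0.838), and with library totals 7 rose and 0 fell, Lpl turned to 0.70 and the calls of Pck1 and Tmem120b ended (-1.15 and -0.26). The call of Cidec (adjusted p = 0.0494) ended without any 1 of the 6 libraries (adjusted p of 0.0744 to 0.137) and with other size factors (0.0509). It also ended with the replicate block (0.117), DESeq2 (0.131), limma-voom (0.108) and no filter (0.0785). That of Fabp4 ended without any but AP replicate 1 (0.0543 to 0.0905) and with limma-voom (0.131). That of Pck1 ended without control replicate 1 or 2 or AP replicate 1 or 2 (0.0695 to 0.21), with DESeq2 (0.063) and with the replicate block (0.0541). Pck1, at -3.27, stood at -6.40 without AP replicate 3 and -2.09 without control replicate 1. Of 9 mesothelial, gut and red cell genes the mesothelial genes Lrrn4 (2.88 ± 0.457, and 3.54 without control replicate 1), Msln, Upk1b (2.65 without control replicate 1, from 2.01), Upk3b and Wt1 (3.60 ± 0.309) rose and Vil1, villin, fell (-3.83 ± 0.307), while the globin gene Hba-a2 was at -0.02 ± 0.362, or 0.56 without control replicate 1 (camera adjusted p = 0.294).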

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

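The entries of the count table without a gene name stayed out of the main comparison, and were kept only in an alternative to it, where some of them differed between the groups. Of 464 such entries that could be tested, 114 were higher and 144 lower in AP than in controls (edgeR, named and unnamed entries fitted together). The 114 took 0.719% of all counts in AP and 0.0371% in controls on average. The largest unnamed entry took 4.84% of the control counts. What these entries are is not known from the table, and no explanation was tested.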

How the results depend on the processing

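The unnamed-entry, repeated-symbol and Bin2, Psmb10 and Prss3b alternatives were chosen after seeing the data. The 8552 called genes were 7839 to 8805 under the alternatives with all libraries except library totals, which gave 12252, and 7654 to 8063 without 1 library (4020 to 4256 higher and 3634 to 3818 lower). The 2-fold count of 5717 was 5515 to 5702 without 1 library and 2886 at a 4-fold threshold. Library totals gave 11680 higher and 572 lower, and 11467 over 2-fold (11030 higher, 437 lower). That fit differs from the main one only in the library sizes, which TMM set at 2.13 times the total in AP and 0.470 times in controls. Which scaling is closer to the amounts in the tissue was not tested. The replicate block gave 7904, although the labels do not pair the numbers. The enzyme share difference of -58.82 points was -59.03 to -58.67 without 1 control and -60.87 to -57.78 without 1 AP library, -62.56 with the acinar list and -67.47 with Bin2, Psmb10 and Prss3b. The 14 list calls became 0 with an estimated correlation (4 at an unadjusted p, while fry, which compares a list with no other genes, made 19 calls), 13 with library totals, and were 14 to 15 without 1 library. Alternatives that apply to normalised values only were not run.

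Of 299 list tests under alternatives, 265 kept direction and call and 8 reversed. Library totals ended 4 list calls (lymphocyte, cytokine, cell cycle and mitochondrial) and gained 3 (regenerating 0.00204, arginine 0.000103 and autophagy 0.0232). With library totals the reversed adjusted p were 0.647 (ductal), 0.164 (adipocyte), 0.378 (mesothelial, gut and red cell) and 0.341 (mitochondrial). The adipocyte list, uncalled throughout, also reversed with fry (0.453), and its adjusted p without 1 library ranged from 0.757 to 0.992 (0.802, 0.813 and 0.777 without control 2, AP 2 and AP 3).

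Of 2708 gene values under alternatives, for 160 genes, 2576 kept direction and call, 69 lost and 25 gained a call, and 38 reversed, 21 of them with library totals. The log2 fold changes that reversed with totals were Itpr3 0.1737, Iapp 1.473, Reg3a 0.135, Reg3b 1.731, Syvn1 0.239, Lpl 0.704, Ndufb5 0.4272, Ndufa4 0.4368, Ndufs3 0.5501, Vamp8 2.163, Cftr 1.06, Hes1 0.6951, Onecut1 0.9641, Bcl2 0.7659, Casp9 0.8533, Stat3 1.992, Gpx4 1.496, Flt1 1.641, Kdr 1.589, Hba-a2 2.159 and Acp5 1.275. Without a filter Vamp8 was at 0.04604 and Hba-a2 at 0.03911, and Hba-a2 was at 0.08609 with limma-voom and 0.1222 with the block. Without 1 library the ranges of genes that reversed, none of them called in the main test, were -0.05585 to 0.0526 (Vamp8), -6.079 to 1.184 (Reg3a), -4.095 to 2.312 (Reg3b), -0.08736 to 1.526 (Cxcl9), -0.08442 to 2.958 (Cxcl11), -0.3351 to 0.1155 (Stat3), -0.3196 to 0.5558 (Hba-a2) and -1.676 to 3.397 (Ifit1). The cause was not tested for these genes. Genes with under 4 counts in a group carry wide counting intervals.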

Other observations

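The gene lists and most tests in this part were chosen after the data had been seen, and only the test over other splits of the samples was planned. Antigen presentation and interferon genes rose. All 11 genes of major histocompatibility complex class II presentation rose, with a median log2 fold change of 4.17, or 3.47 without AP replicate 3 (camera adjusted p = 8.4e-05, adjusted p = 0.231 with an estimated correlation). Cd74, the invariant chain, rose by 3.01 ± 0.313 and RT1-Da by 3.50 ± 0.417. Of 19 interferon-stimulated genes 18 rose, with a median of 3.39 (camera adjusted p = 4.81e-06, adjusted p = 0.231 with an estimated correlation), with Mx1 at 5.19 ± 0.349 and Irf7 at 4.52 ± 0.473 (5.21 without control replicate 2). Ifit1 was not called (2.83 ± 1.59), reached 3.40 and was called without AP replicate 3, and stood at -1.68 without AP replicate 2, since its AP counts were 73, 3514 and 27. All 15 complement genes, 4 of which stand in other lists, rose, with a median of 1.97 (camera adjusted p = 6.32e-06, adjusted p = 0.231 with an estimated correlation), among them C3 (53.9-fold) and Cfb (19.9-fold). Of 13 genes of lipid-laden macrophages, of which Gpnmb, Spp1 and Lpl stand in other lists too, 10 rose and 2 fell, with a median of 3.81 (camera adjusted p = 0.00077, adjusted p = 0.231 with an estimated correlation). Apoe rose to 1738 normalised CPM from 67.7, Plin2 by 4.85 ± 0.335 and Trem2 by 4.89 ± 0.552 (4.26 and 6.08 without control replicates 1 and 2), while Lpl (-1.46 ± 0.251) and Acp5 (-0.91 ± 0.278) fell, and both rose with library totals (0.70 and 1.28). The call of Acp5 ended without control replicate 1 or 3 (adjusted p = 0.0661 and 0.0714).

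Genes of protein synthesis fell relative to other genes. Of 32 cytosolic ribosomal protein genes 31 fell (32 adjusted over the list alone), with a median of -1.30, and 18 of 20 aminoacyl-tRNA synthetase genes fell, with a median of -1.15 (camera adjusted p = 1.91e-11 and 6.32e-06, adjusted p = 0.231 for each with an estimated correlation). Of 13 mitochondrially encoded genes 12 fell, with a median of -1.40 (camera adjusted p = 0.000314, adjusted p = 0.231 with an estimated correlation). With library totals these medians turned to 0.872, 1.02 and 0.775, and the share of counts of ribosomal protein genes was 3.42% ± 0.186 in AP and 2.00% ± 0.26 in controls (SD, n = 3 each).

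The 8552 called genes, 5717 of them over 2-fold, come from comparing AP with control. Of the 10 splits of the 6 samples into 3 and 3, 1 split, the real one, gave as many genes by either count, and the highest of the other 9 splits called 0 genes with edgeR (34 to 93 at an unadjusted p under 0.05), 0 with limma-voom and 4 with DESeq2. With 10 splits, too few exist for a share under 0.05.

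Leukocyte and matrix genes rose while acinar genes fell, and a lower acinar share alone would raise the markers of all other cell types alike. With library totals, the median of the macrophage list lay 4.8 above that of the islet list on the log2 scale. These medians were 5.14 and 0.354 with TMM, so the difference hardly depends on the scaling and restates the list results above. Genes were the units of the 95% bootstrap interval (3.86 to 5.28) and of the permutation p (1e-05, the smallest that 100000 permutations can give). Resampling genes of the same 6 libraries does not measure the spread between samples. The neutrophil, lymphocyte and matrix lists lay 4.81, 2.69 and 1.99 above the islet list. These differences argue against a lower acinar share alone for these 4 lists. The endothelial and adipocyte lists lay -0.0515 and 0.351 from the islet list (permutation p adjusted over the 6 lists = 0.85 and 0.34), so it stays open for them. More blood in the tissue would raise globin, but Hba-a2 was at -0.0199 ± 0.362 (2.16 with library totals, where the macrophage median was 7.32). For this 1 globin gene, that argues against a larger volume of blood like that of controls as the source of the leukocyte transcripts. Globin marks red cells, so more leukocytes within the blood were not tested. Entry of leukocytes into the tissue and induction in resident cells both stay open as hypotheses and cannot be separated in bulk RNA.

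AP replicate 3 kept more digestive enzyme transcripts than the other AP libraries, 4.49-fold to 11.6-fold more over 19 genes. Admixture of control-like acinar RNA, from less affected tissue or from handling, would add the same share of each control transcript. From shares of counts, the RNA of AP replicate 3 that would have to come from such tissue had a median of 9.37% over the genes but ran from 2.61% to 47.7%, and 13 of the 19 genes excluded the median over the spread of the 3 control libraries, which argues against a single admixed share of RNA like these controls. Reg3b took 0.724% of the counts of AP replicate 3, 3.5 times its share in the control library with the most (0.207%). Admixture of RNA like these controls would not by itself give this share. Reg3b also varied widely among the controls (0.00591% to 0.207%). Its value therefore cannot show whether such RNA was admixed. A milder response in this sample stays open and was not tested.

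Bin2, which encodes a membrane-bending protein of leukocytes, and Psmb10, an immunoproteasome subunit gene, fell with the digestive enzymes, for which they were picked. Bin2 fell from 60190 ± 17300 to 309 ± 209 normalised CPM (log2 fold change -7.61, and -8.32 without AP replicate 3) and Psmb10 from 19410 ± 3670 to 224 ± 186 (-6.44, and -7.38 without AP replicate 3), whereas Psmb8 and Psmb9 rose (3.17 and 3.43) and every macrophage list gene rose by at least 1.61. In the other assembly's gene table Psmb10 lies next to Ctrl, a chymotrypsin-like protease gene, and 1 gene lies between Bin2 and Cela1, an elastase gene. Reads of these neighbours counted under the wrong name could give such values. Cela1 and Ctrl were both on the digestive enzyme list, but neither was among its 20 tested members. Bin2 and Psmb10 ranked 11 and 19 by control expression, among the enzyme genes. However, AP replicate 3 held 2.91 times (Bin2) and 3.72 times (Psmb10) the mean of the other AP libraries, below the 4.49-fold to 11.6-fold of all 19 enzyme genes, although reads of the genes' own transcripts would lower these ratios. No read alignments were used here, so misassigned reads and a fall of the genes themselves cannot be told apart.

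Regenerating protein and minor trypsinogen genes varied widely within the groups. Reg3b stood at 4421, 124 and 391 normalised CPM in control replicates 1 to 3 and at 155, 38.8 and 3629 in AP replicates 1 to 3, and Reg1a at 37840, 16210 and 7422 and at 214, 67.6 and 3936. Prss3 stood at 21940, 10280 and 1047 in controls and at 30.1, 16.5 and 215 in AP, and Try5 at 8818, 1377 and 512 and at 82.1, 8.06 and 427, whereas Cpb1 was at 176500, 136600 and 158300 and at 330, 340 and 3237.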
